A study of Mus musculus with 4 samples.

How the data were processed

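Gene expression was measured on Visium arrays in 4 fresh frozen sections of the injured mouse Achilles tendon, 2 from the WT control group and 2 from the F592A 1NMPP1 group, 14 days after injury in mice of 12 weeks. Per the file headers the count matrices were written by Space Ranger 1.3.0, and per the submitters' processing notes the reads were aligned to the genome build mm10 and analysed further in Seurat 3. The deposited matrices hold raw UMI counts per gene and spot with no normalization, for 32285 genes. Tested on the files, their barcodes are the spots marked as under tissue in the deposited positions files, so the counts cover tissue spots alone. The gene identifiers and symbols, spot barcodes and array rows and columns were used as deposited, and the image scale factors were not used. Counts of near-identical gene pairs such as Hba-a1 and Hba-a2 are uncertain, since reads can be split between them.

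Spots with at least 500 UMIs were kept, which left out 4, 3, 3 and 3 spots of WT 1, WT 2, F592A 1 and F592A 2. Regions were found on the kept spots of all sections together with scanpy 1.11.5 (counts scaled to 10000 per spot, log-transformed, 2000 variable genes chosen across sections, values clipped at 10, 30 principal components, 20 neighbours, Leiden resolution 0.6 with leidenalg 0.10.2 and igraph 0.11.9, seed 0), on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0. Figures were drawn with matplotlib 3.10.9. Leading genes of a region were those with the highest fold over the rest after adding 20 CPM. A region was tested when every section held at least 50 of its spots, and 2 of 18 were. The tendon-led region was the tested region with the highest mean share of UMIs from the tenocyte and wound fibroblast lists, and the muscle-led region of the interaction test was the region, of all 18, with the highest share from the fast muscle list. The minimum of 50 spots per section was not applied to the latter, for which WT 2 had 3 spots. A region counted as muscle-led with at least 3 muscle list genes among its 10 leading genes, which held for 4 regions.

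Spots are not replicates, so UMI counts were summed per section over all kept spots or over the spots of a region, and the section was the replicate. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr) on R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each SE is the absolute log2 fold change over the square root of the F statistic, and CPM values are counts scaled to a common library size, with TMM factors except for sums over lists. The interaction test fitted the group by region term on 8 sums with the section as a block. Its residual degrees of freedom were 2 per gene and its prior degrees of freedom infinite, against 3.72 for whole sections and 4.86 for the tendon-led region. Region shares were compared with an exact two-sided permutation test, for which 2 sections against 2 give no p under 0.3333. Section pairs were compared by the chi-square of gene counts per degree of freedom, and by the overlap of region shares. The chi-square was not scaled for depth and grows with it. The 4 libraries held 30154873 to 43957617 UMIs, so counting error is small for genes above a few CPM.

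The 42 gene lists, 23 of cell type markers and 19 of pathways, were fixed before the data were examined, as were the comparisons, tests, thresholds and rule for named genes. Ccl21a, Aldoa and Ca9 were not among the files' symbols. Lists with at least 3 tested genes, 41 of them, were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 41, and again with an estimated correlation and with fry. Counts adjusted over the list alone apply Benjamini-Hochberg within the list. In whole sections the rule named up to 12 genes per direction with the largest fold change among those past the threshold, with a mean log2 CPM of at least 5 and both sections of one group above both of the other, filled to 8 per direction by smallest p and said not to pass. The tendon-led region took 10 per direction filled to 6, the other tested region 3, and each list up to 4 members by smallest p. A fixed set of genes, among them Ngfr, Scx, Tnmd, Tppp3, Tgfb1 and Col1a1, was named in any case.

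The fits were tested on simulated counts with 200 changed genes before they were run on the files. For whole sections (16145 genes) 89% of genes changed by 2-fold and 100% of those changed by 4-fold were recovered with 6 false calls. For the tendon-led region (13947 genes) it was 83% and 100% with 8 false calls, and for the interaction (13177 genes) 8% and 60% with 5 false calls. Each simulated gene took its spread from the common trend, and genes at low CPM were not changed. These shares therefore do not measure recovery in the files, where genes differ in spread. The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, leaving out each section, a block by section number, all spots or at least 1000 UMIs, muscle-led spots or muscle, haemoglobin and mitochondrial genes left out, Leiden resolutions 0.3 and 1.0, and components centred per section. Added after seeing the data were spots with at least 2% of UMIs from the tenocyte and wound fibroblast lists in place of the region, spots of the region with under 1% from the muscle lists, and the hair follicle-led region in place of the muscle-led one in the interaction. The labels' section numbers are shared across groups without a stated pairing, and sequence reads and images were not examined.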

Results

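The data were spatial transcriptomes of the mouse Achilles tendon injury site, taken 14 days after a punch biopsy of 0.5 mm was made about 2 mm above the tendon's attachment to the heel bone. Visium arrays captured the RNA of each section on a grid of barcoded spots, and each value was a count of unique molecular identifiers (UMIs) per gene and spot. There were 4 sections of 10 µm, 2 from TrkA WT control mice and 2 from TrkA F592A mice given 1NMPP1. TrkA is a receptor kinase of many sensory and sympathetic neurons, and the F592A substitution makes it sensitive to the drug 1NMPP1. The comparison asks how the tissue around the injury differs when TrkA signalling is blocked. Genotype and drug changed together, and the labels do not say whether the WT mice received the drug. The labels give 4 pooled mice per genotype and both sexes, but do not tie sections to animals, so the p-values measure only the spread between sections. WT 1 held 42911141 UMIs over 3047 tissue spots, WT 2 held 30154873 over 2027, F592A 1 held 43957617 over 2837 and F592A 2 held 37089208 over 2751. The median spot held 5974, 7932, 5468 and 6540 UMIs in the same order. All folds are F592A over WT, each mean stands with its SD over 2 sections, and each log2 fold change with its standard error (SE).

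Ngfr, a neurotrophin receptor of Schwann cells and some fibroblasts, was at 5.46 ± 0.113 CPM (UMI counts scaled to a common library size) in WT and 2.83 ± 0.743 CPM in F592A whole sections. Its log2 fold change was −0.95 ± 0.24 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.267), which did not pass the test. The fixed list of neurotrophins and receptors had a median log2 fold change of −0.11 over 7 tested genes, with a camera adjusted p of 0.958. UMI counts do not show a substitution, so the genotype of the sections was not checked.

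RNA from the sex chromosomes parted 1 section from the other 3. Xist, which is transcribed from the inactive X chromosome of females, gave 4207 UMIs in WT 2 and 7 to 12 UMIs in the other sections. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together gave 23 UMIs in WT 2, 7918 in WT 1, 7723 in F592A 1 and 7522 in F592A 2. The Y-linked list accordingly had a median log2 fold change of 1.06 in whole sections (camera adjusted p = 0.034, and adjusted p = 0.612 with an estimated correlation). Camera's adjusted p was 0.755 without WT 2 and 0.0658 without F592A 1, and sex differed within the WT pair as well as between groups. The list for X inactivation held too few tested genes for a test.

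The sections held different amounts of muscle, skin, nerve and tendon. Spots of the 4 sections together fell into 18 regions, each called here by its leading genes. A region led by Ecm1, Prelp, C4b and Cd248, genes of fibrous connective tissue, had the highest share of UMIs from the tenocyte and wound fibroblast lists among regions present in every section, and is called the tendon-led region. It covered 9.88 ± 7.61% of WT and 10.3 ± 2.92% of F592A spots, a difference of 0.402 percentage points (exact two-sided permutation test, p = 1.0). A region led by embryonic and slow muscle genes (Myh3, Myl4, Sln, Myh8, Tnni1, Myh7) covered 11 ± 3.94% of WT and 0.782 ± 0.540% of F592A spots. A region led by Krt77, Lor, Krtdap and Lce1m, genes of the epidermis, covered 1.88 ± 1.18% and 8.03 ± 0.428%. Another epidermal region, with Krt2, Flg, Krt10 and Krt1 among its leading genes, had 229 of its 236 spots in WT 1. The Krt77-led share alone therefore does not measure a section's epidermis. A region led by fast muscle genes (Myh4, Pvalb, Tnnt3) covered 6.24 ± 8.61% of WT and 16.7 ± 0.194% of F592A spots, with 3 spots in WT 2. Another fast muscle region, led by Mss51 and Myh1, covered 8.2 ± 5.4% and 0.747 ± 0.491%, with 243 spots in WT 2. Neither share alone therefore measures a section's fast muscle. Another slow muscle region, led by Myl3 and Myl2, covered 4.27 ± 5.90% and 6.44 ± 0.52%. For the regions led by Myh3, Krt77, Myh4 and Mss51 the exact permutation test gave p = 0.3333, the smallest that 2 sections against 2 can give.

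**Figure D1:**
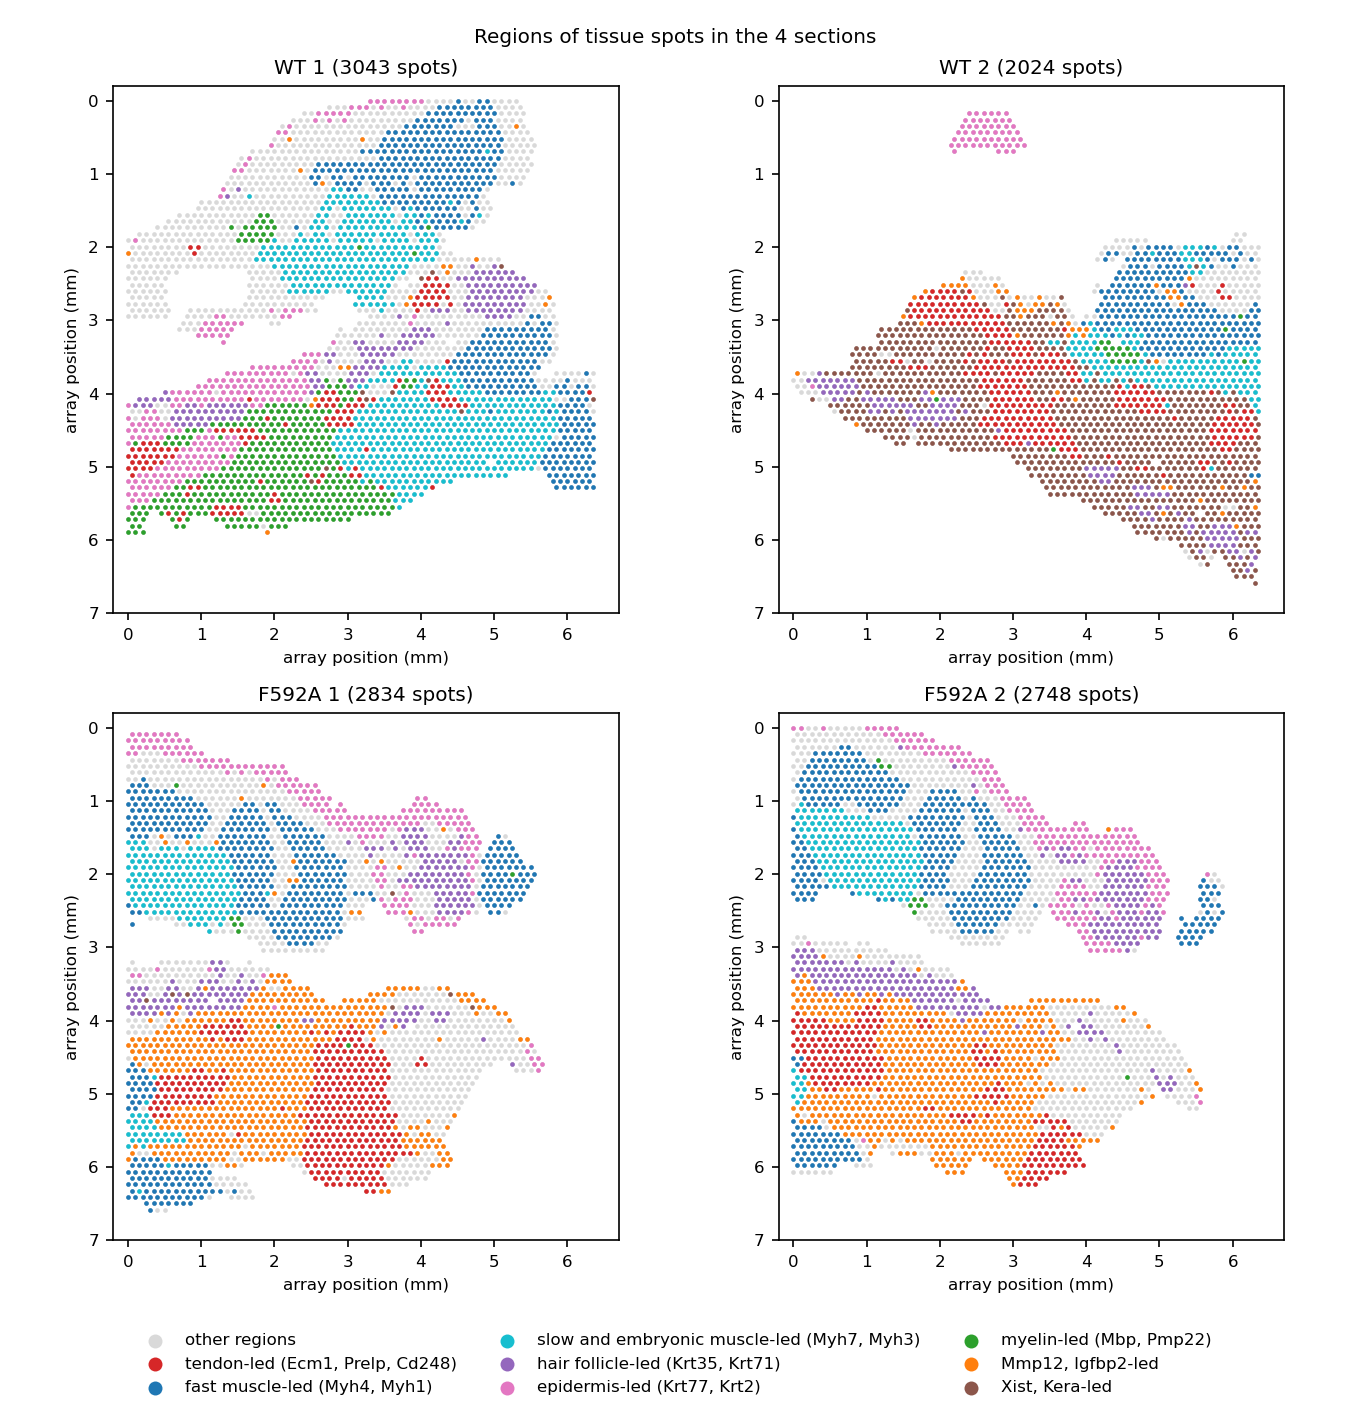
Each panel maps the tissue spots of 1 section by array position in mm, coloured by region, with regions named by leading genes. The tendon-led region covered 137 spots in WT 1, 309 in WT 2, 350 in F592A 1 and 226 in F592A 2, and the F592A maps show a similar arrangement of muscle, skin and Mmp12-led tissue.

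Several regions belonged almost to 1 section or 1 group. The region led by Xist, Kera, Matn4 and Cilp2 had 888 of its 906 spots in WT 2, and a region led by myelin genes, Mbp and Pmp22 among them, had 409 of its 449 spots in WT 1. A region led by Mmp12 and Igfbp2 covered 22.8 ± 2.35% of F592A and 1.65 ± 1.45% of WT spots (exact permutation p = 0.3333). The F592A pair shared 89.8% of its region composition, whereas the other 5 pairs of sections shared 23.3% to 40.0%. The chi-square per degree of freedom between gene counts was 27.3 for the F592A pair, 54.6 for the WT pair and 51.4 to 71.2 for the pairs across groups. Every group difference reported for these sections stands beside that closeness of the F592A pair.

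In whole sections, Sln, Myh7, Igf2, Chrdl1 and Clu were lower in F592A, and Krt77, Lce1m, Ptgs2 and Ccn1 were higher. Sln, a regulator of the muscle calcium pump, fell from 122 ± 11.8 to 6.24 ± 0.853 CPM (log2 fold change −4.28 ± 0.15, edgeR's adjusted p = 0.00351). Myh7, the slow myosin heavy chain, fell from 329 ± 2.50 to 60.9 ± 5.55 CPM (−2.43 ± 0.12, edgeR's adjusted p = 0.0126). The growth factor Igf2 fell from 155 ± 46.0 to 15.7 ± 4.41 CPM (−3.31 ± 0.29), the BMP antagonist Chrdl1 from 57.6 ± 1.25 to 20.8 ± 2.74 CPM (−1.47 ± 0.12) and the chaperone Clu from 123 ± 7.47 to 44.8 ± 6.04 CPM (−1.45 ± 0.13). Krt77, a keratin of the sweat duct and epidermis, rose from 34.6 ± 8.36 to 322 ± 56.3 CPM (3.22 ± 0.22), and the cornified envelope gene Lce1m from 16.2 ± 1.80 to 79.6 ± 18.7 CPM (2.30 ± 0.19). Ptgs2, which encodes the inducible cyclooxygenase, rose from 5.55 ± 0.574 to 28.4 ± 1.34 CPM (2.36 ± 0.13, edgeR's adjusted p = 0.0133), and the matrix signalling gene Ccn1 from 88.8 ± 0.422 to 241 ± 28.9 CPM (1.44 ± 0.12). The adjusted p by edgeR was 0.0333 for Krt77. For each of Igf2, Chrdl1, Clu, Lce1m and Ccn1 it was 0.0491, just under the threshold of 0.05.

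By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13 of 16347 genes passed 0.05, 5 higher and 8 lower, and 1927 had an unadjusted p under 0.05. In each of the 13, both F592A sections lay on the same side of both WT sections. The test itself favours such genes, and 44.2% of all tested genes had that order, against 33.3% by chance. The other called genes, named after their values were seen, were Nfil3 (higher) and Adam23, Kcnk1 and Chga (lower). Just outside the threshold stood Tnnt1 at −2.18 ± 0.20 (edgeR's adjusted p = 0.0521), Peg3 at −1.03 ± 0.10 (0.0638) and Sema3b at −0.93 ± 0.09 (0.0786). On the positive side stood Per1 at 1.14 ± 0.13 (0.0976), Ier3 at 0.76 ± 0.09 (0.118), Adamts1 at 0.71 ± 0.09 (0.127), Cebpd at 0.86 ± 0.11 (0.127) and Myc at 1.01 ± 0.13 (0.129). Among genes chosen in advance, Tnmd, Scx and Col1a1, markers of tendon cells and their matrix, had log2 fold changes of −1.30 ± 0.32 (edgeR's adjusted p = 0.251), −0.44 ± 0.13 (0.302) and −0.30 ± 0.39 (0.808). The tendon sheath gene Tppp3 was at 0.31 ± 0.17 (0.561) and Tgfb1 at −0.14 ± 0.11 (0.689). The count rested on the F592A pair and on the method: edgeR called 0 genes without F592A 1 (1441 at an unadjusted p under 0.05) and 0 without F592A 2 (835), but 349 without WT 1 and 390 without WT 2. DESeq2 called 420 on all 4 sections. RLE scaling gave 5 calls, which did not include Igf2, Chrdl1, Clu, Lce1m or Ccn1. Leaving out muscle-led spots gave 8, of which 4 were among the 13. There Sln, Myh7, Clu, Chrdl1, Ccn1 and Lce1m no longer passed, though all 13 kept their direction. Leaving out mitochondrial, haemoglobin and muscle genes gave 4, and dropping the filter on low counts gave 546.

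Camera with its preset correlation called the slow and regenerating muscle lists lower and the fast muscle list higher in whole sections. All 8 slow muscle genes had negative log2 fold changes, with a median of −2.14 (camera adjusted p = 4.1e-41), 1 called over all genes (Myh7) and 7 when adjusted over the list alone, among them Tnni1 at −2.50 ± 0.34 and Tnnc1 at −2.09 ± 0.29. All 10 genes of the stem cell and regenerating muscle list were negative, with a median of −2.87 (6.2e-14), 0 called over all genes by edgeR and 7 adjusted over the list alone, among them Myh3, the embryonic myosin, at −6.36 ± 0.81. The fast muscle list had a median of 0.29 with 12 of 14 genes positive (0.00118), 0 called either way, and Pvalb at 0.58 ± 0.18 and Myh4 at 0.46 ± 0.18. Adjusted p = 0.498 with an estimated correlation for each of these lists. Without WT 2 the fast muscle list's camera adjusted p was 0.191.

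The tenocyte list was lower by camera in the F592A whole sections, and the collagen list did not pass the test. Of 10 tenocyte genes, 9 were negative, with a median of −1.15 (camera adjusted p = 1.6e-14, and adjusted p = 0.498 with an estimated correlation), 0 called over all genes and 9 adjusted over the list alone. Examples were Chad at −1.77 ± 0.25, the transcription factor Mkx at −1.36 ± 0.20 and the fibril-binding proteoglycan Fmod at −1.0 ± 0.24. The tendon sheath and progenitor list had a median of 0.28 with 9 of 11 genes positive (0.0018, and adjusted p = 0.612 with an estimated correlation), 0 called either way, and without WT 1 its camera adjusted p was 0.684. The collagen fibril list had a median of −0.11 (0.562), matrix proteases and inhibitors −0.13 (0.776) and wound fibroblasts 0.14 (0.201). Chondrocyte genes had a median of −0.53 (0.0529), osteoblast genes −0.13 (0.899) and osteoclast genes −0.20 (0.629).

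By camera the class II list and several immune cell lists were lower, and the acute inflammation and neutrophil lists higher, in the F592A whole sections. All 7 class II genes were negative with a median of −0.84 (camera adjusted p = 3.7e-14), 0 called over all genes by edgeR and 6 adjusted over the list alone (Cd74, H2-Aa, H2-Ab1, H2-DMa, H2-DMb1 and H2-Eb1). The T and NK cell list fell with a median of −0.83 (5.0e-06) with 4 of 10 genes called when adjusted over the list alone, among them Cd4 at −1.40 ± 0.22, and the B and plasma cell list fell with a median of −0.62 (0.0139). The acute inflammation list rose with a median of 0.67 (7.3e-08), with Ptgs2 called over all genes and 5 adjusted over the list alone (Cxcl2, Il1b, Il1rn, Il6 and Ptgs2). The neutrophil list had a median of 0.78 (0.00068) and 0 called either way. For each of these 5 lists adjusted p = 0.498 with an estimated correlation. The mast cell list had a median of −0.87 (0.00076, and adjusted p = 0.541 with an estimated correlation). Macrophage genes had a median of 0.04 (0.634), myeloid precursors −0.04 (0.370) and interferon response genes 0.08 (0.425). The B and plasma cell list did not pass without WT 2 (0.0932) or without F592A 1 (0.126), and the neutrophil list did not pass without WT 2 (0.0600).

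In the F592A whole sections, camera with its preset correlation called the Schwann and myelin list lower and the adipocyte, keratinocyte and immediate early lists higher. The Schwann and myelin list had a median of −1.69 (camera adjusted p = 1.2e-12) with 11 of 12 genes negative, 0 called over all genes and 9 adjusted over the list alone, among them Mbp at −2.25 ± 0.43 and Pmp22 at −0.99 ± 0.20. Mbp stood at 115 ± 72.2 CPM in WT and 24.1 ± 1.7 CPM in F592A, and the myelin-led region lay mostly in WT 1. The adipocyte list had a median of 1.16 (5.0e-06) and 6 genes adjusted over the list alone, the immediate early list 0.36 (2.1e-05) and 3 (Atf3, Dusp1 and Junb), and the glycolysis list 0.33 (5.0e-06) with all 13 genes positive and 0. The endothelial list had a median of −0.31 (0.00013) with Cldn5 adjusted over the list alone, and the erythroid list −0.72 (0.00068). For these 6 lists adjusted p = 0.498 with an estimated correlation. The keratinocyte list had a median of 0.65 (3.4e-05) and the cell cycle list 0.22 (0.0106), both with adjusted p = 0.612 with an estimated correlation, and the lymphatic list −0.58 (0.00501, and adjusted p = 0.603 with an estimated correlation). Without WT 2 the keratinocyte (0.128), cell cycle (0.202) and lymphatic (0.116) lists did not pass, and without F592A 1 neither did cell cycle (0.0768) and lymphatic (0.163).

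Of 41 lists tested in whole sections, 10 rose and 11 fell by camera with its preset correlation, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and 0 by fry (6 at an unadjusted p under 0.05). The remaining lists did not pass: axon genes had a median of 0.14 (camera adjusted p = 0.363), sensory neuropeptides and receptors −0.20 (0.370), mural cells −0.15 (0.702), angiogenic factors 0.15 (0.776), BMP signalling −0.08 (0.958), heat shock −0.05 (0.961) and oxidative phosphorylation 0.02 (0.958). For TGF-beta signalling (median −0.13, camera adjusted p = 0.853), Wnt signalling (−0.06, 0.958) and the mitochondrial genome (−0.02, 0.776), the median was negative and camera's direction was up.

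**Figure D2:**
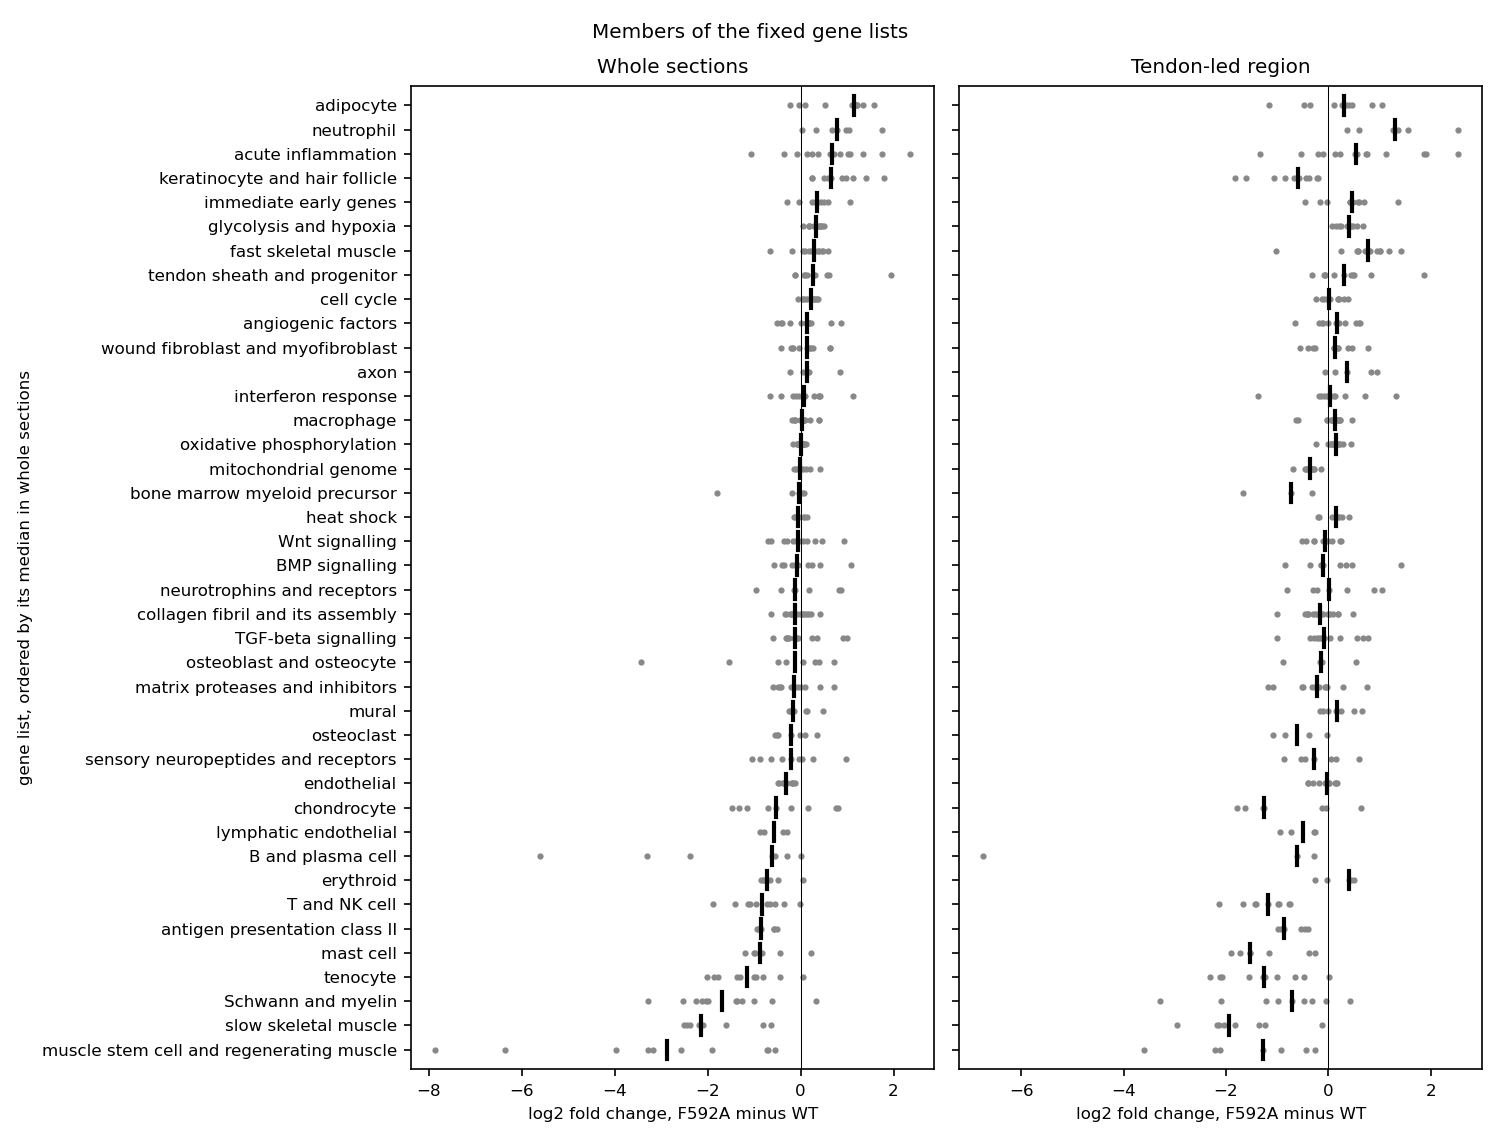
Points are the log2 fold changes (F592A minus WT, x axis) of the tested members of each fixed gene list (y axis), and black bars are medians, in whole sections and in the tendon-led region. Slow muscle genes have medians of −2.14 and −1.93, tenocyte genes −1.15 and −1.26, and the keratinocyte and erythroid medians lie on opposite sides of 0 in the 2 panels.

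Within the tendon-led region, Nr4a1, Errfi1, Ccn1 and Il1b were among the genes that rose in F592A, and Kera, Cilp2, Mmp14 and Igf2 among those that fell. The nuclear receptor Nr4a1 rose from 49.7 ± 4.62 to 160 ± 33.1 CPM (log2 fold change 1.68 ± 0.16, edgeR's adjusted p = 0.0252), and the EGFR inhibitor gene Errfi1 from 18.5 ± 2.07 to 49.7 ± 5.58 CPM (1.43 ± 0.14). Ccn1 rose from 113 ± 21 to 293 ± 5.08 CPM (1.38 ± 0.15), Ier3 from 45.4 ± 1.86 to 88.7 ± 5.22 CPM (0.97 ± 0.10), the transcription factor Cebpd from 66.9 ± 7.15 to 125 ± 5.45 CPM (0.90 ± 0.12) and the angiotensin-converting enzyme Ace from 86.0 ± 4.81 to 153 ± 8.0 CPM (0.83 ± 0.11). Il1b, an inflammatory cytokine, rose from 2.35 ± 0.214 to 8.56 ± 0.0945 CPM (1.87 ± 0.22, edgeR's adjusted p = 0.0414). These Il1b values rest on only 21 and 28 UMIs in WT 1 and WT 2, and on 232 and 144 in F592A 1 and F592A 2. The proteoglycan Kera fell from 204 ± 57.4 to 47.0 ± 5.05 CPM (−2.12 ± 0.20, edgeR's adjusted p = 0.0252) and Cilp2 from 135 ± 24.3 to 31.8 ± 3.22 CPM (−2.08 ± 0.15, edgeR's adjusted p = 0.0161). The collagenase-activating protease Mmp14 fell from 735 ± 123 to 325 ± 14.6 CPM (−1.18 ± 0.15), the secreted antioxidant enzyme Gpx3 from 946 ± 30.8 to 360 ± 78.4 CPM (−1.39 ± 0.17) and Cpxm2 from 332 ± 11.7 to 163 ± 1.22 CPM (−1.03 ± 0.11). In whole sections Mmp14 was at −0.59 (edgeR's adjusted p = 0.282). Kera, Cilp2 and Mmp14 were also among the leading genes of a region with 888 of 906 spots in WT 2. Mmp14 was also a leading gene of the Mmp12-led region, with 598 and 671 of its 1342 spots in F592A 1 and F592A 2. Igf2 fell from 120 ± 30.1 to 16.9 ± 5.59 CPM (−2.82 ± 0.26), Clu by a log2 change of −2.15 ± 0.26, Chrdl1 by −1.81 ± 0.23, Myh2 by −1.03 ± 0.12 and the Wnt receptor Fzd8 by −0.91 ± 0.11.

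By edgeR's test 36 of 14125 genes passed 0.05 after Benjamini-Hochberg adjustment, 9 higher and 27 lower, with 1624 at an unadjusted p under 0.05, and 10 of the 36 were also called in whole sections (Adam23, Ccn1, Chga, Chrdl1, Clu, Igf2, Kcnk1, Myh7, Nfil3 and Sln). For each of the 36, both F592A sections lay on the same side of both WT sections, an order that the test favours. Of all genes tested in the region, 44.2% had it, against 33.3% by chance. Of the genes chosen in advance, Tnmd was at −1.28 ± 0.21 (edgeR's adjusted p = 0.106), Scx at −0.47 ± 0.18 (0.400), Col1a1 at −0.46 ± 0.20 (0.435), Tppp3 at 0.84 ± 0.21 (0.256), Ngfr at −0.80 ± 0.41 (0.508) and Tgfb1 at −0.18 ± 0.11 (0.577), none past the threshold. The count was 70 without WT 1, 78 without WT 2, 43 without F592A 1 and 19 without F592A 2, with 26, 24, 16 and 10 of the 36 called again. DESeq2 called 172. Without F592A 1 the calls lost included Mmp14, Clu, Cebpd and Ier3, and without F592A 2 Ccn1, Errfi1, Gpx3 and Mmp14. Il1b, Ace and H2-Eb1 were among the calls lost whichever section was left out. With the spots chosen by their tenocyte and wound fibroblast score in place of the region, a choice added after seeing the data, edgeR called 1 gene (2189 at an unadjusted p under 0.05) and 0 of the 36, while all 36 kept their direction. With no filter on low counts it called 893.

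**Figure D3:**
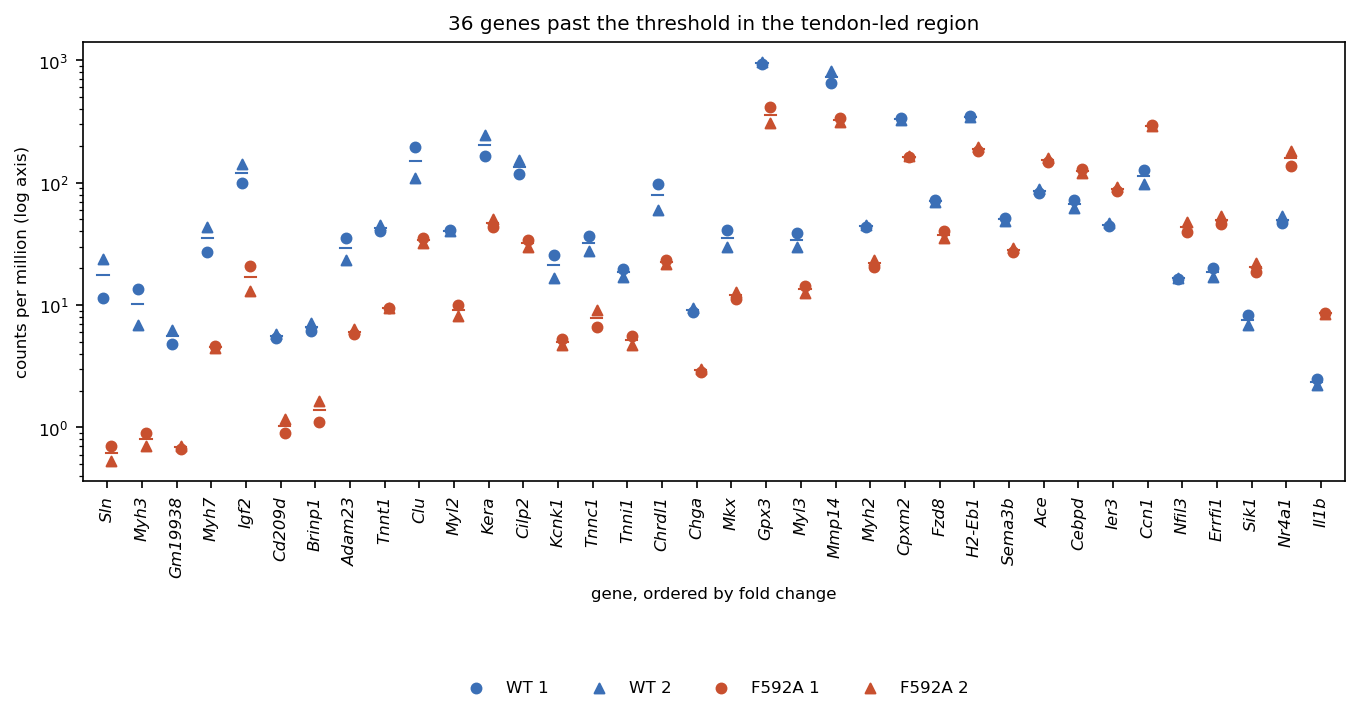
CPM values on a log axis are shown for the 36 genes past the threshold in the tendon-led region, ordered by fold change on the x axis, with 1 point per section and a bar at each group mean. In every gene the 2 F592A points lie on one side of the 2 WT points, as for Cilp2, with means of 135 in WT and 31.8 in F592A.

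In the tendon-led region, camera with its preset correlation called the slow muscle list lower and the fast muscle list higher. Of 8 slow muscle genes, all negative with a median of −1.93 (camera adjusted p = 1.3e-55, adjusted p = 0.149 with an estimated correlation, and fry adjusted p = 0.0155), 6 were called lower over all genes (Myh7, Myl2, Myl3, Tnnc1, Tnni1 and Tnnt1) and 7 when adjusted over the list alone. Tnnt1 fell from 42.7 ± 3.50 to 9.42 ± 0.0206 CPM and Myh7 from 35.2 ± 11.3 to 4.54 ± 0.159 CPM. The fast muscle list had a median of 0.77 (1.4e-13, and adjusted p = 0.415 with an estimated correlation), with Myh2 called lower over all genes and 10 higher and 1 lower adjusted over the list alone. Its direction turned in the spots chosen by score, where the median was −0.24. The list for regenerating muscle had a median of −1.28 (1.0e-07, and adjusted p = 0.354 with an estimated correlation) with Myh3 called and 5 adjusted over the list alone. These muscle transcripts stood in spots of a tendon-led region, where the fast list summed to 1624 and 1974 CPM in WT and 2631 and 3275 CPM in F592A before TMM scaling.

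By camera the tenocyte and class II lists were lower in the tendon-led region as well. Of 10 tenocyte genes 9 were negative, with a median of −1.26 (camera adjusted p = 5.6e-32, and adjusted p = 0.226 with an estimated correlation), 3 called over all genes (Cilp2, Kera and Mkx) and 9 adjusted over the list alone. Beside this, the Kera-led regions outside it, of 906 and 64 spots, had 888 and 60 in WT 2, and the Mmp12-led region covered 1.65% of WT and 22.8% of F592A spots. Fmod was at −1.24 ± 0.19 (edgeR's adjusted p = 0.0797) and Chad at −2.31 ± 0.42 (0.139). The chondrocyte list had a median of −1.25 (0.00279) and 3 lower and 1 higher adjusted over the list alone, and all 7 class II genes were negative with a median of −0.87 (1.0e-15), H2-Eb1 called (346 ± 2.78 to 189 ± 11 CPM) and 6 adjusted over the list alone. The Schwann and myelin list had a median of −0.70 (0.00011) and 5 adjusted over the list alone. For these 3 lists adjusted p = 0.354 with an estimated correlation. The collagen list had a median of −0.16 with 15 of 20 genes negative (0.0251, and adjusted p = 0.415 with an estimated correlation), only Col11a1 adjusted over the list alone, and it did not pass without WT 1 (0.0710) or without F592A 1 (0.147). The T and NK cell list had a median of −1.17 (2.0e-05) and the mitochondrial genome −0.35 (4.5e-06), each with adjusted p = 0.530 with an estimated correlation, and the T and NK cell list did not pass without WT 2 (0.332). The mast cell list had a median of −1.53 (0.0001, and adjusted p = 0.419 with an estimated correlation) and the keratinocyte list −0.58 (0.00951, and adjusted p = 0.619 with an estimated correlation), the latter not passing without WT 1 (0.0514) or without F592A 1 (0.108).

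By the same test the immediate early, acute inflammation and neutrophil lists were higher in the tendon-led region. The immediate early list had a median of 0.46 (camera adjusted p = 3.2e-05) with 0 called over all genes by edgeR and 7 adjusted over the list alone (Atf3, Btg2, Dusp1, Egr1, Ier2, Jun and Junb), among them Atf3 at 1.35 ± 0.27. The acute inflammation list had a median of 0.54 (0.00011) with Il1b called and 3 adjusted over the list alone, and the neutrophil list 1.31 (1.8e-06) with 3 adjusted over the list alone (Cxcl2, S100a8 and S100a9). For each of these 3 lists adjusted p = 0.354 with an estimated correlation. The tendon sheath list had a median of 0.32 (0.00101, and adjusted p = 0.530 with an estimated correlation) with Has1, Ly6a and Tppp3 adjusted over the list alone, and did not pass without WT 1 (0.185). The glycolysis list had a median of 0.40 (2.0e-05) and the axon list 0.36 (0.0486), each with adjusted p = 0.419 with an estimated correlation, the oxidative phosphorylation list 0.14 (0.0368, and adjusted p = 0.619 with an estimated correlation) and the Y-linked list 1.09 (0.0271, and adjusted p = 0.588 with an estimated correlation). Without WT 1 the axon list (0.335), and without WT 2 the oxidative phosphorylation (0.367) and Y-linked (0.977) lists, did not pass, nor did axon without F592A 2 (0.437) or oxidative phosphorylation without F592A 1 (0.0967).

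Of 41 lists in the tendon-led region, 9 rose and 11 fell by camera, 0 passed with an estimated correlation (5 at an unadjusted p under 0.05) and 1, slow muscle, by fry (9 at an unadjusted p under 0.05). The lists that did not pass included wound fibroblasts (median 0.13, camera adjusted p = 0.296), macrophages (0.14, 0.135), TGF-beta signalling (−0.09, 0.778), matrix proteases (−0.22, 0.0622, with Mmp14 called), interferon response (0.03, 0.560), neurotrophins and receptors (0.02, 0.841) and sensory neuropeptides (−0.29, 0.890, where camera's direction was up).

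The other region with enough spots in every section was led by the hair follicle keratins Krt35 and Krt71 and by Gjb2. It covered 5.81 ± 0.451% of WT and 8.09 ± 2.15% of F592A spots (exact permutation p = 0.3333). Here Krt77 rose from 46.4 ± 3.8 to 494 ± 76.3 CPM (log2 fold change 3.43 ± 0.35, edgeR's adjusted p = 0.0031), the only call among 11408 genes, with 494 at an unadjusted p under 0.05. Krt77 also led an epidermal region whose share was 1.88% in WT and 8.03% in F592A, while a Krt2-led epidermal region lay almost wholly in WT 1. Over both tested regions together edgeR's count was 37. Without F592A 1 the Krt77 call in this region was not kept.

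The test of whether changes differed between tissues set the tendon-led region against the fast muscle-led region led by Myh4. By edgeR's test of the region by group interaction, 158 of 13587 genes passed 0.05 after Benjamini-Hochberg adjustment, 138 with a more positive change in muscle-led spots and 20 with a more negative one, and 1036 had an unadjusted p under 0.05. Fitted separately, Clu had a log2 fold change of −2.13 in tendon-led and −0.17 in muscle-led spots, and the joint fit gave a difference of 2.38 ± 0.31 (edgeR's adjusted p = 4.5e-11), and Gpx3 was at −1.37 and 0.06, a difference of 1.51 ± 0.41 (edgeR's adjusted p = 0.0254). WT 2 gave the muscle-led region only 3 spots with 23438 UMIs, and the fit took every gene's spread from the common trend, so these p-values understate it. The count was 39 without WT 1 and 78 without F592A 2. Without WT 2 it was 179, of which 52 were more negative in muscle-led spots.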

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

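The tests of group, of sex, of muscle content and of tissue handling, and the comparison with the hair follicle-led region, were chosen only after the result was seen.

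Changes between F592A and WT differed between tissues by edgeR's test of the region by group interaction. Against the tendon-led region, 158 genes differed in the fast muscle-led region and 20 in the hair follicle-led region, with 1036 and 853 at an unadjusted p under 0.05. The difference in log2 fold change, muscle-led minus tendon-led, was 2.38 ± 0.31 for Clu (edgeR's adjusted p = 4.5e-11), 1.96 ± 0.47 for Sln (0.00513), 1.51 ± 0.41 for Gpx3 (0.0254) and 1.62 ± 0.47 for Cilp2 (0.0477). Hair follicle-led minus tendon-led, it was 2.32 ± 0.33 for Krtdap (edgeR's adjusted p = 0.000305), 2.89 ± 0.50 for Fosb (0.00549) and 2.02 ± 0.41 for Krt77 (0.0319). For Igkc, an immunoglobulin gene, it was 6.09 ± 0.75 (edgeR's adjusted p = 6.5e-05), but 1043 of its tendon-led UMIs were in WT 2, against 11 in WT 1, 7 in F592A 1 and 10 in F592A 2. The muscle-led fit took the spread of every gene from the common trend, so its p-values understate it, and WT 2 had 3 spots in the muscle-led region. The hair follicle-led fit had 25.7 prior degrees of freedom.

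The F592A sections resembled each other more than any other pair of sections. Aligned by layout, their region labels gave a kappa of 0.4361, and the highest of the other 5 pairs 0.1498. Sections of one tissue (one animal, or neighbouring cuts of a block) could give this. But kappa is capped where sections share few regions, as in the other 5 pairs, so it partly restates the shared composition. The layout correlation of marker list maps, which uses no region labels, was 0.78 for the F592A pair. For the other 5 pairs it ran from 0.454 to 0.701, the latter for WT 1 with F592A 2. Sex as the whole cause is argued against by WT 1, which had Y-linked RNA like the F592A sections and a depth between theirs. It still lay at 51.4 and 63.5 in chi-square per degree of freedom from them, against 27.3 between them. WT 2, with Xist RNA, was 1.104 times as far from them as WT 1. That ratio does not decide, since the measure grows with depth and WT 2 held the fewest UMIs. The WT pair was 1.063 times as far apart as the closest pair across groups, a ratio that the lower depth of WT 2 also affects. An effect in F592A alone needs no closeness of the WT pair, so the group and a shared tissue cannot be told apart. If one animal gave both F592A sections, the spread within F592A may be smaller than between animals, and the labels leave this open.

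Slow and embryonic muscle genes were lower in the F592A sections, in whole sections and in the tendon-led region. Less skeletal muscle in those sections is argued against, since the fast muscle list had a median log2 fold change of 0.2908. Slow muscle lying next to the WT tendon, with RNA spread into neighbouring spots, may account for part of the change in tendon-led spots. With Atp2a2 left out, as set beforehand, the log2 ratio for the slow list was −2.144 under 2 spot spacings from muscle-led spots. It was −1.812 at 2 to under 5 and −1.008 at 5 or more. Over the section pairs the last value ran from −0.575 to −1.378, so at this number of sections spread RNA and a change in the tendon tissue cannot be told apart. The fast muscle list went the other way in the same bands, with log2 ratios of 1.719, 1.213 and 1.045. At 5 or more it summed to 596 and 1309 CPM in WT and to 1829 and 2101 CPM in F592A. With Atp2a2, the slow list summed to 450 and 446 CPM in WT over the whole tendon-led region, and to 276 and 293 CPM in F592A. Its ratio by distance with Atp2a2 was not computed. A difference in which muscle each section caught, or in muscle regeneration between the groups, stays open and was not tested.

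The 9 genes called higher in the tendon-led region of the F592A sections included Nr4a1, Errfi1 and Ccn1. They were chosen by their rise in tendon-led spots, so that rise cannot be weighed against their change in other tissues. Handling before freezing could reach all tissues: the median log2 ratio of the 9 genes was 1.447 in tendon-led, 0.794 in keratin-led and 0.453 in muscle-led spots, with both F592A sections above both WT sections for 9, 5 and 6 genes. Ier3 at −0.55 and Nfil3 at −0.101 went the other way in muscle-led spots, as did Ace at −0.516 in keratin-led spots, and handling and group cannot be told apart, since each group's sections could have been handled together. Collection at another time of day may also raise such genes, but the difference between the medians of clock genes of opposite phases was 0.216 (0.172 against −0.044), between the values that would have decided it. The groups' genotype and drug stay open.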

How the results depend on the processing

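The low-muscle spots, the spots chosen by score and the hair follicle-led region were tests chosen only after the result was seen. For genes in whole sections the count of 13 became 420 with DESeq2, 5 with RLE scaling, 546 with no filter on low counts, 8 without muscle-led spots (4 of the 13 called again), 4 without mitochondrial, haemoglobin and muscle genes, and 0 to 390 with each section left out in turn, where the group left with 1 section is assumed to vary like the other. For the tendon-led region 36 became 172 with DESeq2, 893 with no filter, 1 with spots chosen by score (0 of the 36 called again) and 19 to 78 with each section left out, and was 38 with RLE scaling, 39 and 33 at Leiden resolutions 0.3 and 1.0, and 29 in low-muscle spots, with 36, 32, 27 and 28 of the 36 called again. Over both tested regions 37 became 173 with DESeq2, 935 with no filter, 106 at resolution 0.3 and 99 with components centred per section (both with 4 tested regions), and 27 to 528 with each section left out. The interaction count of 158 became 20 with the hair follicle-led region and 39 to 179 with each section left out, with a median log2 shift of 7.97 over all genes without WT 1, which leaves the 3 muscle-led spots of WT 2 as the only WT sum. The list counts of 21 and 20 became 0 and 0 with an estimated correlation and 0 and 1 by fry, and ran from 16 to 22 and from 19 to 23 with each section left out. Every gene called in whole sections or in the tendon-led region kept its direction under each alternative that gave it a value. Among the named genes of whole sections and the tendon-led region, no value past the threshold in the main or the alternative setting changed direction. Of all comparisons of named genes, 2138 kept their side of the threshold, 207 passed it newly and 90 no longer passed. Genes outside the named set that were called only under an alternative were not compared in this way. Changes of direction in genes past it in neither setting were not counted. The share of the tendon-led region differed by 0.402 percentage points between groups, by 0.018 to 1.745 under resolutions and spot filters and by 11.033 with components centred per section. That setting gave no gene count for the tendon-led region, whose matched region had no spots in WT 2. Apart from the numbers of genes, samples or regions entering a fit, the cause was not tested. Depth limits genes under about 1 CPM in whole sections, higher levels in the region sums, and the muscle-led sum of WT 2. The hair follicle-led sums held only 489766 UMIs in WT 2 and 723231 in F592A 1.

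The section numbers are shared between the groups without a stated pairing. With the number as a block, edgeR called 7 genes in whole sections, 95 in the tendon-led region and 125 over both regions, and 21 and 25 lists. The deviations of sections with the same number had a correlation across genes of −0.1354 in whole sections and −0.04234 in the tendon-led region, and genes are not independent replicates.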

Other observations

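The test of imprinted genes was planned before their values were seen, on a list chosen after Igf2, Peg3 and Gpc3 had been noticed.

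With the spots of muscle-led regions left out, the slow muscle list had a median log2 fold change of −1.88 in whole sections, the regenerating muscle list −1.77, the Schwann and myelin list −2.19, the tenocyte list −1.12 and the class II list −0.92. With an estimated correlation their adjusted p were 0.0995, 0.378, 0.509, 0.430 and 0.492, in this order. In the same spots the wound fibroblast list had a median of 0.27 (camera adjusted p = 0.00175, and adjusted p = 0.588 with an estimated correlation), which did not pass without WT 1 (0.156) or without F592A 1 (0.220).

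A wider set of imprinted growth genes may be lower in the F592A sections, as a hypothesis. Of 14 imprinted genes measured in whole sections apart from Igf2 and Peg3, 10 were lower, 9 of them with both F592A sections under both WT sections. The median log2 fold change of the 14 was −0.554. Beside them, the regenerating muscle list had a median of −2.87, and the region led by Myh3 and Myh8 covered 11% of WT and 0.782% of F592A spots. Cdkn1c was at −0.71 (edgeR's adjusted p = 0.196), H19 at −0.66 (0.386), Peg10 at −0.76 (0.244) and Zdbf2 at −3.08 (0.224), and Nnat at 1.2 (0.282), so none passed by itself. The share of genes that were lower fell between the bounds set in advance, so these 14 genes do not decide it.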
